A study of Arabidopsis thaliana with 4 samples.

How the data were processed

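RNA-seq was made from 14-day-old Arabidopsis thaliana seedlings of the wild type Col-0 and of mos2-2, a line in the Col-0 background with a T-DNA insertion in MOS2, grown with 16 h of light and 8 h of dark. Poly(A) RNA was purified and sequenced on an Illumina GAIIx, per the labels' protocols. There were 2 libraries per genotype. The labels do not say whether the libraries of a genotype came from separate cultures, so p-values measure only the spread between these libraries, which may be technical in part. Clock genes differed between same-genotype libraries by a median absolute log2 of 2.14 in Col-0 and 1.99 in mos2-2. Reference genes differed by 0.18 and 0.27. For the clock genes this argues against libraries made from 1 RNA sample, but does not show separate cultures. No pair of libraries held identical values.

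The deposited values are FPKM per gene, made by the authors with TopHat and Cuffdiff on the TAIR10 build, per the submitters' processing notes. Versions, annotation release, strand setting and the treatment of reads with several matches are not given in the sources used here. Each library listed 33557 loci, and 8594 of them were at 0 in every library. Names, transcript lengths and gene types came from the TAIR10.1 annotation, in which 32810 of the loci were matched and 747 were not. The coordinates of MOS2 are those of TAIR10.1. Counts of reads were not used. An exact 0 in such files can be a failed estimate, so a gene without a value above 0 is described as listed at 0 and no fold is given against it.

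FPKM values keep a trace of depth, because many low values lie near whole multiples of what 1 read is worth, though others, such as those of MAPR2 in Col-0, do not. From low genes compared between libraries, Col-0 replicate 1 had a relative depth of 0.63 against Col-0 replicate 2, and mos2-2 replicates 1 and 2 had 1.005 and 1.038. One read in a 1000 nt transcript was worth 0.216, 0.138, 0.138 and 0.131 FPKM in Col-0 replicates 1 and 2 and mos2-2 replicates 1 and 2, which corresponds to about 4600000, 7300000, 7300000 and 7600000 reads. For short genes, a curve of the FPKM of 1 read against transcript length was fitted to snoRNA values and scaled by those depths. Of 128 snoRNA values under 5.5 reads, 89.8% came out within 0.1 of a whole number of reads, against a mean of 19.3% over 1000 shuffles of the lengths. The curve was fitted to these same values and was not refitted in the shuffles, so this contrast is in part set by the fit. Among 43 values of miRNA genes left out of the fit the share was 39.5%, against 11.3% with shuffled lengths, so read numbers are estimates and are weaker for miRNA genes. This curve replaced a first one, fitted per library to snoRNA and miRNA genes together, which was discarded because only 28.6% to 51.5% of its values came out whole. The 39.5% of the left-out miRNA values lies within that range, so it does not favour the second curve. The median number of reads behind the short genes past the threshold was 5.4 with the first curve, which had been seen before the change, and 2.0 with the second.

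Expression was compared with limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), for the 19236 genes with a mean of at least 1 FPKM, with genotype as the only term, a mean-variance trend in the empirical Bayes step, two-sided tests and a Benjamini-Hochberg adjusted p threshold of 0.05. Values were used as deposited, with no further scaling. The fit had 2 residual degrees of freedom and a prior of 2.84. Log2 differences are on the log2(FPKM + 1) scale, which understates the change of low genes. Folds are ratios of mean FPKM. Gene lists were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the 20 lists with at least 3 genes past the filter. Camera with an estimated correlation and fry stand beside it. The spread between replicates within lists was counted after seeing the data. The model was tested on simulated data for this comparison over 19236 genes. Of 50 genes changed at each size, it recovered 0% of 2-fold, 60% of 4-fold, 96% of 8-fold and 94% of 16-fold changes, with 12 false calls, and 2 of 100 unchanged lists had an unadjusted p below the threshold. Noise was drawn separately for each gene, so the simulation held no correlation between genes and no steps of whole reads. It cannot show how lists of co-regulated genes behave. Its recovery may not hold in these data, where MOS2, 26.3-fold lower in mos2-2, did not pass.

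The design, the gene lists and the rule for named genes were fixed before the data were examined. In each direction the rule takes up to 12 genes with the largest change among those past the threshold without overlap between genotypes. Remaining places go to the smallest unadjusted p among genes with a mean of at least 5 FPKM and no overlap, described as not passing. Members of the miRNA, TAS, tasiRNA target and miRNA biogenesis lists may be named, and up to 4 members of each other list by smallest p. PAD3, CYP71A13, PR1, CCA1, LHCB2.1, LHCB2.2, AT2G24945, AT2G23120 and AT3G41979, and the members of the mitochondrial and DNA damage lists apart from AT2G04050, fall outside the rule and were chosen after their values were seen. Alternatives were pseudocounts of 0.1 and 5, no filter, a mean of at least 5 FPKM, median-ratio scaling, quantile normalization, the replicate number as a block, no trend, robust empirical Bayes, and each library left out in turn. Nuclear genes of at least 300 nt, with and without the block, were added after seeing the data. Figures were drawn with matplotlib.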

Results

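The experiment asked how the transcriptome of seedlings differs when MOS2, an RNA-binding protein that the study ties to microRNA maturation, is disrupted. Poly(A) RNA was compared between 2 Col-0 and 2 mos2-2 libraries. The deposited FPKM summed to 1350292 and 1393563 in Col-0 replicates 1 and 2 and to 1388613 and 1522916 in mos2-2 replicates 1 and 2. Between 22411 and 23009 genes were above 0 per library. Pearson's r of log2(FPKM + 1) across 19236 genes, which are not independent replicates, was 0.897 between the Col-0 libraries and 0.924 between the mos2-2 libraries. Between genotypes it ran from 0.887 to 0.917, so libraries of a genotype were not clearly closer to each other than to the other genotype.

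MOS2 (AT1G33520) transcripts were far lower in mos2-2. The gene lies on chromosome 1 from 12157054 to 12159125 on the minus strand of TAIR10.1, with 1 annotated transcript of 1 exon and 2072 nt. Its level was 50.3 and 36.9 FPKM in the Col-0 libraries and 2.16 and 1.16 FPKM in the mos2-2 libraries, or 43.6 ± 9.48 against 1.66 ± 0.706 FPKM (SD, n = 2 each), 26.3-fold lower. The log2 difference was -4.08 (SE 0.31). The limma adjusted p over all genes was 0.0727, which did not pass the threshold. Both mos2-2 libraries lay below both Col-0 libraries.

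**Figure D1:**
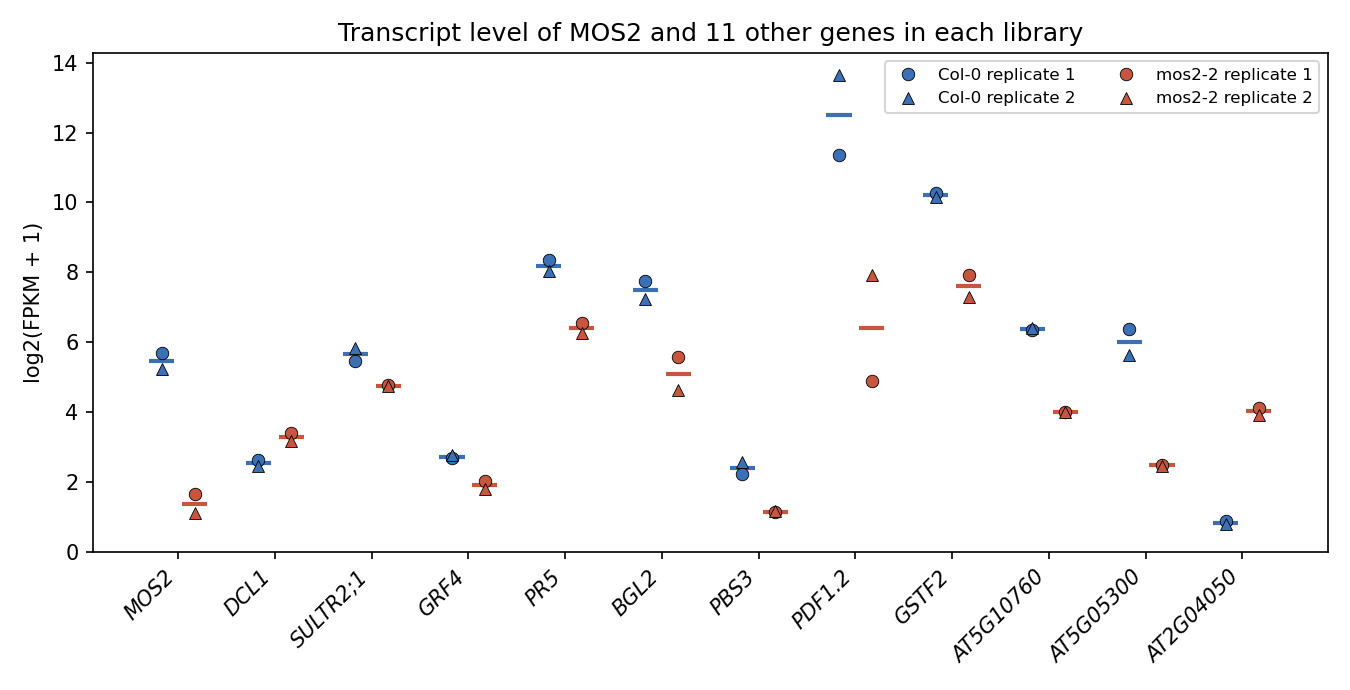
Level of MOS2 and 11 other genes in each library as log2(FPKM + 1), with Col-0 in blue, mos2-2 in red, circles for replicate 1, triangles for replicate 2 and bars for the mean of the 2 libraries. MOS2 lies at 50.3 and 36.9 FPKM in Col-0 and at 2.16 and 1.16 FPKM in mos2-2.

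Across all genes, 12 passed the limma threshold, 10 higher and 2 lower in mos2-2. Most were very short non-coding RNAs. The higher genes included the snoRNA genes AT2G35382, AT1G03746, AT2G43138, AT1G75163 and AT3G58193 and the tRNA genes AT1G60840 and AT4G08345. They also included AT2G23118, of 144 nt, the chloroplast locus ATCG01030, and MAPR2 (AT2G24940). The lower genes were MIR413 and AT5G10336, whose values were identical in every library. AT1G75163 was listed at 0 in both Col-0 libraries and at 263 and 248 FPKM in mos2-2 (adjusted p 0.00342), and AT2G35382 was listed at 0 in Col-0 and at 326 and 764 FPKM (adjusted p 0.022). The 5.8S rRNA locus AT3G41979, also not an mRNA, was at 23211 and 20656 FPKM in Col-0 and at 73081 and 76744 FPKM in mos2-2. MIR413 had a mean of 32.1 FPKM over the 2 Col-0 libraries and was listed at 0 in both mos2-2 libraries (adjusted p 0.0424). Of the 12 genes, 9 were under 150 nt, where 1 read was worth 126 to 208 FPKM at 80 nt, and these 9 genes held a median of 2.0 reads per library where they were above 0. AT5G10336 shared the values of MIR413, which held an estimated 1.0 read in each Col-0 library. ATCG01030, whose length was not matched, had the same 131 FPKM in mos2-2 replicate 1 as AT3G58193, there an estimated 1.01 reads. Both calls may thus also rest on very few reads. AT2G23118 lies antisense within AT2G23120, and reads of the pair cannot be told apart without a stated strand. With any 1 library left out the limma count was 0, and 819 to 1790 genes had an unadjusted p under 0.05. Such a fit has 1 residual degree of freedom and a lone library in 1 genotype, which is assumed to vary like the other genotype, so the lost calls do not show that the 12 are unstable.

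**Figure D2:**
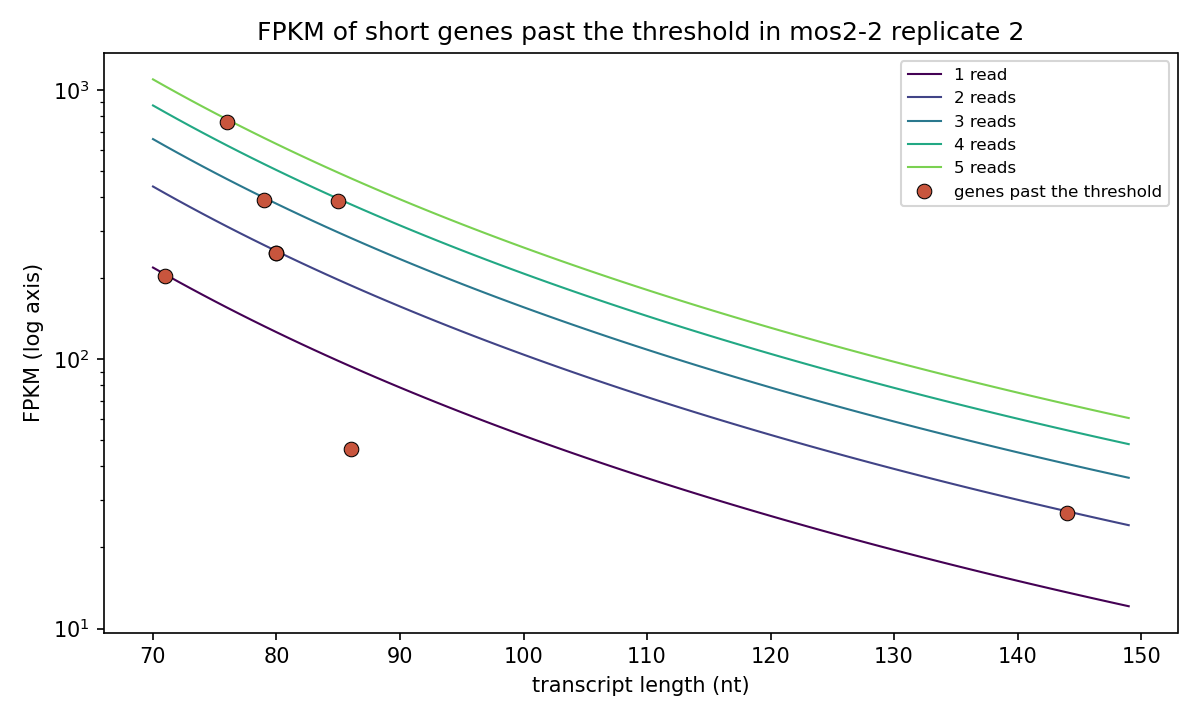
FPKM on a log axis against transcript length in nt for the genes under 150 nt that passed the threshold and were above 0 in mos2-2 replicate 2, with lines for the FPKM of 1 to 5 reads. The points lie on or near whole numbers of reads except AT4G08345, at 46.3 FPKM and an estimated 0.49 reads. The lines were fitted to snoRNA values, so for the 5 snoRNA genes among the points this is in part set by the fit.

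MAPR2 was near 0 in Col-0, at 0.004 and 0.085 FPKM, and at 41.6 and 79.8 FPKM in mos2-2 (limma adjusted p 0.0424). Its neighbour AT2G24945 ran the other way, at 79.1 and 81.8 FPKM in Col-0 and at 44.2 FPKM in mos2-2 replicate 1, and was listed at 0 in mos2-2 replicate 2. The sum of both genes was 79.1, 81.9, 85.8 and 79.8 FPKM, so the value of MAPR2 is uncertain.

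Apart from MAPR2, no nuclear gene of at least 300 nt passed the threshold. Restricted to the 18534 nuclear genes of at least 300 nt, a restriction chosen after seeing the data, limma called 0 genes, while 1397 had an unadjusted p under 0.05 where 927 would by chance. The same count was 1493 with the libraries split by replicate number and 320 with the crossed split (Col-0 replicate 1 and mos2-2 replicate 2 against the other libraries), so the excess is not particular to genotype. The genes that the naming rule took by their small unadjusted p differed several-fold, and the following did not pass. GSTF2 and GSTF3, glutathione S-transferases, were 5.95-fold and 6.31-fold lower in mos2-2. GSTF2 was at 1230 and 1146 FPKM in Col-0 and at 243 and 156 FPKM in mos2-2. AT5G10760 stood at 82.7 ± 2.83 against 15.0 ± 0.0564 FPKM (SD, n = 2 each), 5.52-fold lower in mos2-2. AT5G05300 was 14.3-fold lower, at 81.8 and 49.2 FPKM in Col-0 and 4.66 and 4.51 FPKM in mos2-2. UGT71B6, a glucosyltransferase of abscisic acid, was 5.76-fold lower and AT3G01830 was 4.46-fold lower. In the other direction AT2G04050, a MATE-type transporter gene, was 19.5-fold higher, at 0.84 and 0.735 FPKM in Col-0 and 16.4 and 14.3 FPKM in mos2-2 (limma adjusted p 0.0727).

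As a description without a test, 923 genes differed at least 2-fold on the log2(FPKM + 1) scale without overlap, 220 higher and 703 lower in mos2-2. With quantile normalization the split was 303 higher and 554 lower. The median difference over all genes was -0.091 as deposited and 0.013 after quantile normalization. Splitting the same 4 libraries by replicate number instead gave 1055 genes at least 2-fold apart without overlap, more than the genotypes did. Of all genes tested, 37.8% did not overlap between genotypes, 37.7% between replicate numbers and 23.4% in the crossed split, where chance gives 33.3%.

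Because the study concerns microRNA maturation, transcripts targeted by microRNAs were examined as a group. They did not move together. Of 124 listed targets 93 were tested, 45 higher and 48 lower in mos2-2, with a median log2 difference of -0.09. None passed the limma threshold over all genes or adjusted over the list alone, and 1 was higher and 2 were lower at an unadjusted p under 0.05. The fit recovered 0% of 2-fold changes in the simulation, so the absence of calls does not exclude changes of that size. DCL1, the nuclease that processes microRNA precursors and itself a target of miR162, stood at 4.89 ± 0.512 against 8.85 ± 1.15 FPKM. The sulfate transporter gene SULTR2;1, a miR395 target, stood at 49.8 ± 9.68 against 26.1 ± 0.352 FPKM, and GRF4, a miR396 target, at 5.62 ± 0.284 against 2.81 ± 0.411 FPKM (SD, n = 2 each). The copper/zinc superoxide dismutase gene CSD1, a miR398 target, was at 454 and 328 FPKM in Col-0 and 154 and 264 FPKM in mos2-2. The SPL targets of miR156 divided into 5 higher and 6 lower, and all 5 TCP targets of miR319 were lower, with differences from -0.28 to -0.02. The camera adjusted p of the list was 0.648 with direction up, against the sign of the median. Camera compares a list with the other genes tested, and the median over all genes was -0.091. Its direction is therefore relative to those genes and does not by itself mean higher or lower than in Col-0.

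Transcripts of microRNA genes themselves were mostly too low to test. Of 178 genes 51 passed the filter, 22 higher and 29 lower, with a median of -0.08 and quartiles of -1.40 and 1.75. Many of the 51 were above 0 in only 1 library. MIR777 was at 63.9 FPKM in Col-0 replicate 1, where 1 read at its 108 nt was worth an estimated 63.9 FPKM. MIR393a was at 18.6 FPKM in mos2-2 replicate 1, where 1 read at its 133 nt was worth an estimated 18.6 FPKM. The division and the median rest in part on such values and cannot show that these transcripts did not shift. MIR413 passed over all genes and adjusted over the list alone, on an estimated 1.0 read in each Col-0 library, and was listed at 0 in mos2-2. MIR822 stood at 7.50 and 3.78 FPKM in Col-0, at 0.94 FPKM in mos2-2 replicate 1 and was listed at 0 in mos2-2 replicate 2, and did not pass. The camera adjusted p was 0.668 with direction up, against the sign of the median, and the direction turned with a mean of at least 5 FPKM (adjusted p 0.899), median-ratio scaling (0.866), quantile normalization (0.686), genes of at least 300 nt (0.35), and without Col-0 replicate 1 (0.0819) or mos2-2 replicate 2 (0.963). Without mos2-2 replicate 1 the list passed with direction up (adjusted p 0.0338).

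The 5 tested TAS transcripts, precursors of trans-acting siRNAs, were all lower, 4 of them without overlap, with a median of -0.49. TAS2 stood at 12.4 ± 2.91 against 6.93 ± 1.55 FPKM (SD, n = 2 each) and TAS3 at 38.4 ± 3.82 against 32.9 ± 3.02 FPKM. No transcript passed, and the camera adjusted p was 0.111. The list passed without a filter on low values (camera adjusted p 0.00435), while with an estimated correlation the adjusted p was 0.864. Of 4 tested tasiRNA targets 3 were lower, including ARF2 and ARF4, and ETT was higher (camera adjusted p 0.751). Of 22 genes of microRNA biogenesis and function 16 were higher and 6 lower, with a median of 0.10 (camera adjusted p 0.111). HYL1 was at 10.4 ± 0.482 against 10.6 ± 1.13 FPKM and AGO1 at 36.1 ± 7.64 against 30.1 ± 1.87 FPKM. The 14 tested genes of the siRNA pathway divided evenly, 7 higher and 7 lower (camera adjusted p 0.648).

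Salicylic acid defence genes were lower as a group in mos2-2 by camera at the preset correlation, but not past the adjusted threshold with an estimated correlation. Of 21 tested members 19 were lower, 11 of them without overlap, with a median of -0.56 and a camera adjusted p of 0.000181. With an estimated correlation the adjusted p was 0.849 (unadjusted 0.0425), and fry gave p = 0.0316. Adjusted over the list alone 5 members passed, and over all genes none did. In 11 of the 21 the Col-0 replicates lay further apart than the genotype means, and in 8 the mos2-2 replicates did. In the same libraries the 5.8S rRNA locus AT3G41979 was at 23211 and 20656 FPKM in Col-0 and at 73081 and 76744 FPKM in mos2-2. PR5, a pathogenesis-related protein gene, stood at 293 ± 45.8 against 84.8 ± 12.6 FPKM, 3.45-fold lower, and BGL2, a beta-glucanase gene also called PR2, at 182 ± 47.1 against 35.3 ± 16.0 FPKM, 5.16-fold lower (SD, n = 2 each). PBS3 was 3.50-fold lower and NIMIN1 also 3.50-fold lower, and PAD3 was 4.91-fold lower. CYP71A13 was among the 2 higher members, 1.35-fold with overlap. PR1 varied within mos2-2, at 764 and 25.3 FPKM, against 150 and 155 FPKM in Col-0. It is among the 19 counted as lower on the log2(FPKM + 1) scale (-0.116), although its mean FPKM was 2.59-fold higher in mos2-2.

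Jasmonate and ethylene defence genes did not pass as a group (25 tested, 18 lower, camera adjusted p 0.293). The 3 near-identical defensin genes PDF1.2, PDF1.2b and PDF1.2c, among which reads may have been divided, passed adjusted over the list alone. PDF1.2 was at 2632 and 12697 FPKM in Col-0 and at 28.7 and 240 FPKM in mos2-2. JAZ3, a repressor of jasmonate signalling, was 1.80-fold higher and did not pass.

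On the log2(FPKM + 1) scale all 28 photosynthesis genes were higher in mos2-2, 10 of them without overlap, with a median of 0.63 and a camera adjusted p of 1.68e-07. Those 10 are no larger a share than the 37.8% of all genes tested that did not overlap between genotypes. By mean FPKM, PSAD-2 (0.907-fold) and RBCS2B (0.965-fold) were slightly lower in mos2-2 and the others higher. With an estimated correlation the adjusted p was 0.864, and fry gave p = 0.366. No member passed over all genes or adjusted over the list alone. The call ended without Col-0 replicate 1. That library was the shallowest, but whether its depth was the cause was not tested. In 23 of the 28 the Col-0 replicates lay further apart than the genotype means, and in 9 the mos2-2 replicates did. The widest was LHCB2.1, at 42.2 and 3051 FPKM in Col-0 and at 632 and 5084 FPKM in mos2-2. The 5.8S rRNA locus was also higher in both mos2-2 libraries, at 73081 and 76744 against 23211 and 20656 FPKM. PSBP-1 was at 2084 and 3719 FPKM in Col-0 and at 4205 and 5439 FPKM in mos2-2, and RBCS3B stood at 5560 ± 1350 against 8470 ± 126 FPKM (SD, n = 2 each).

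**Figure D3:**
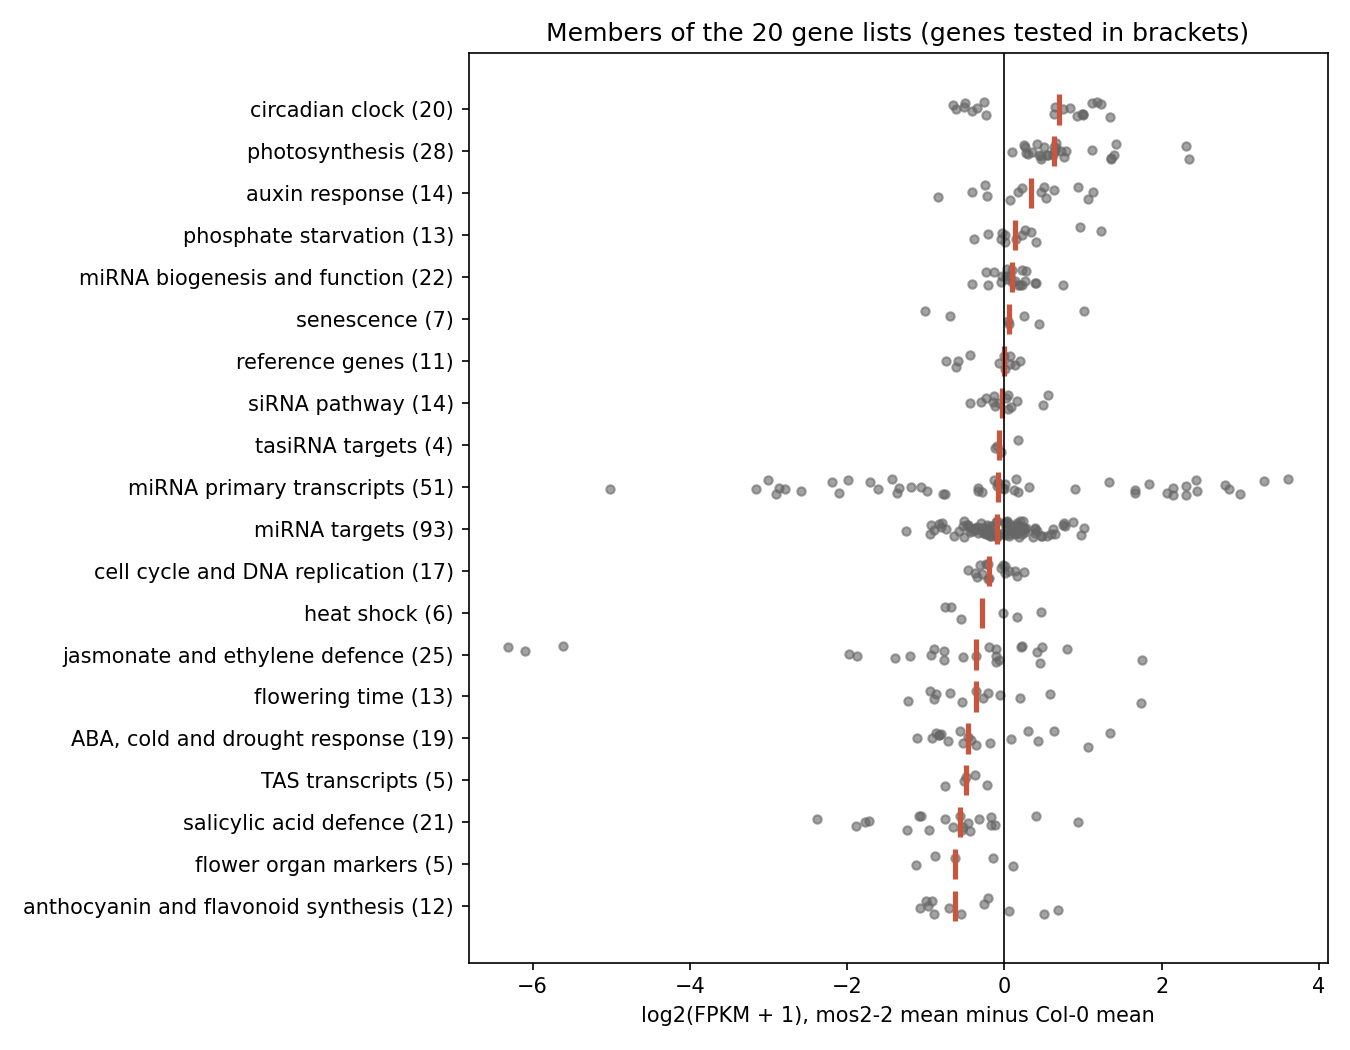
Difference of mean log2(FPKM + 1) between mos2-2 and Col-0 for each tested member (grey points, spread vertically for legibility) of 20 gene lists, with the list median as a red bar and the number of genes tested in brackets. The 28 photosynthesis genes lie above 0, with a median of 0.63, and 19 of 21 salicylic acid defence genes lie below 0, with a median of -0.56.

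The remaining lists did not pass camera. Anthocyanin and flavonoid genes were mostly lower (9 of 12, adjusted p 0.16), with DFR at 11.6 and 13.1 FPKM in Col-0 and 5.52 and 5.88 FPKM in mos2-2. Auxin response genes were higher in 10 of 14 cases (adjusted p 0.143), with IAA2 at 152 ± 19.6 FPKM in Col-0 and 346 ± 146 FPKM in mos2-2 (SD, n = 2 each). Among flowering time genes (adjusted p 0.615), the floral repressor FLC stood at 3.12 and 2.67 FPKM in Col-0 and at 20.8 and 6.70 FPKM in mos2-2, while MAF1 was 2.39-fold and AGL31 1.88-fold lower. Clock genes (adjusted p 0.175) and phosphate starvation genes (adjusted p 0.615) had no member past the threshold over all genes or adjusted over the list alone. The same was true of ABA, cold and drought response (0.668), heat shock (0.648), senescence (0.668), cell cycle and DNA replication (0.767), flower organ markers (0.648) and reference genes (0.669), with the camera adjusted p in brackets. Of the root markers only SHR and SCR were tested, both lower, and no seed storage gene passed the filter. Reference genes had a median of -0.01 and quartiles of -0.51 and 0.07, with 5 higher and 6 lower. Of them 1, ACT8, was lower at an unadjusted p under 0.05, at 112 and 112 FPKM in Col-0 and 76.7 and 57.1 FPKM in mos2-2. UBQ10 was 1.48-fold, AT5G15710 1.49-fold and, with overlap, ACT2 1.60-fold lower. Fry for changes in either direction gave an unadjusted p = 0.00151, so these genes cannot be taken as unchanged.

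Within 500 kb of MOS2 on chromosome 1, 7 of 129 tested genes (5.4%) had an unadjusted limma p under 0.05, against 1343 of 19106 elsewhere (7.0%), a difference that was not detectable (two-sided Fisher's exact p = 0.604). The 12 genes past the adjusted threshold are too few for such a comparison, and 0 of them lay within the window.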

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

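The restriction to nuclear genes of at least 300 nt was chosen after seeing the data. The causes of the changes below were not tested, except that fewer libraries or genes entered where stated. The 12 genes past the threshold became 4 with a pseudocount of 5, 4 without a filter, 7 without the trend, 0 with genes of at least 300 nt and 0 with any 1 library left out, where 1 residual degree of freedom is left and a lone library is assumed to vary like the other genotype. The replicate number shared by the genotypes is no stated pairing. Deviations of same-numbered libraries correlated across genes with r = 0.211, and with the replicate number as a block 6 genes passed, and the clock list passed with direction up (adjusted p 0.0293). With genes of at least 300 nt and the block 8 passed, MOS2 among them (adjusted p 0.0232), and 4 other lists passed instead of 2, adding the clock (0.0143) and auxin (0.0444). The 923 genes at least 2-fold apart became 388 with a pseudocount of 5, 603 with a mean of at least 5 FPKM, and 1453 to 2245 with 1 library left out.

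The MOS2 difference kept its direction in every alternative run. The miRNA target list never passed, and turned direction without mos2-2 replicate 2 (adjusted p 0.872; range with 1 library left out 0.283 to 0.927). The miRNA primary transcripts turned direction with a mean of at least 5 FPKM (adjusted p 0.899), median-ratio scaling (0.866), quantile normalization (0.686), genes of at least 300 nt without (0.35) and with the block (0.136), and without Col-0 replicate 1 (0.0819) or mos2-2 replicate 2 (0.963). Without mos2-2 replicate 1 they passed with direction up (0.0338). Of the other lists 2 passed, against 0 with an estimated correlation, 3 without a filter, where the TAS transcripts were added (0.00435), 3 with the block and 2 to 6 with 1 library left out. Salicylic acid defence stayed lower and past the threshold in every alternative of camera at the preset correlation. It did not pass with an estimated correlation, and its fry p of 0.0316 was not adjusted over the lists. The call thus rests on the preset correlation.

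Lists that did not pass also turned direction. The tasiRNA targets did without a filter (adjusted p 0.929). Other lists turned direction with 1 library left out, and their adjusted p then ranged widely. Without Col-0 replicate 1 the lists for the clock (range 0.000519 to 0.473), auxin (0.00189 to 0.938), cell cycle (0.194 to 0.963), phosphate starvation (6.23e-09 to 0.963), senescence (0.0979 to 0.986) and flower organs (0.0104 to 0.877) turned. Phosphate starvation passed in opposite directions without Col-0 replicate 1 (3.22e-05, lower) and without Col-0 replicate 2 (6.23e-09, higher), and turned without mos2-2 replicate 2. Without Col-0 replicate 2 the ABA (0.000936 to 0.883) and heat shock lists (0.282 to 0.86) turned. The ABA list too passed in opposite directions, without Col-0 replicate 1 (0.000936, lower) and without Col-0 replicate 2 (0.00619, higher). Without mos2-2 replicate 1 the jasmonate (0.00848 to 0.86), anthocyanin (0.000204 to 0.766), senescence and flower organ lists turned. Of 330 comparisons of named genes, 239 kept direction and side of the threshold, 85 lost the threshold, 6 gained it and 0 reversed. Named genes that did not pass in the main fit cannot lose the threshold, and they count as kept unless they gained it. All 85 losses therefore fell on the 12 genes that had passed, so the 239 do not show that those calls were stable. At this depth 1 read in a short gene can decide a call.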

Other observations

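The tests of reads per short gene, of MAPR2 and of the clock genes were chosen only after the result was seen. The mitochondrial and DNA damage lists were drawn up after 4 and 1 of their genes had stood out, and those genes were left out of the tests. The p-values of both lists are unadjusted.

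Several genes of the mitochondrial dysfunction response, which plants induce when respiration is impaired, were higher in mos2-2, although none passed the limma threshold over all genes. AT2G21640 stood at 15.2 ± 0.786 FPKM in Col-0 and 113 ± 14.5 FPKM in mos2-2 (SD, n = 2 each), 7.41-fold higher, and AT5G51440, a mitochondrial small heat shock protein gene, at 1.32 ± 0.581 against 22.9 ± 9.39 FPKM. A hypothesis is that a wider set of these genes is higher in mos2-2. Of 12 tested members not seen before, 9 were higher, 7 without overlap, with a median log2 difference of 1, limma camera p = 2.68e-05, p = 0.0475 with an estimated correlation and fry p = 0.00207. The tested members include AT2G04070, 3.74-fold higher, and DTX1 (AT2G04040), 1.29-fold higher with overlap. Both are close in locus number to AT2G04050, which prompted the list, so they may not be independent of that choice. AOX1A, the alternative oxidase, was 2.15-fold higher and NAC13 2.86-fold higher, while BCS1 was 2.46-fold lower. A single library did not carry the difference, since the lowest median with 1 library left out was 0.69. The data do not say whether this is an effect of the mutation or of another difference between the seedlings, which the design cannot separate.

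NAC044, a DNA damage response gene, was at 0.184 FPKM and listed at 0 in the Col-0 libraries and at 9.24 and 11.6 FPKM in mos2-2. The hypothesis that a wider set of DNA damage response genes is higher gave limma camera p = 9.27e-05 at the preset inter-gene correlation. With an estimated correlation p was 0.0566 and fry gave p = 0.055. Of 7 tested members not seen before 6 were higher, with PARP2 3.41-fold and GMI1 4.01-fold higher. The median of 0.57 became 0.24 without Col-0 replicate 2 and 1.07 without Col-0 replicate 1.

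Genes under 150 nt made up 9 of the 12 genes past the threshold, among them 5 snoRNA, 2 tRNA and 1 miRNA gene. These genes held a median of 2.0 reads per library where above 0, so a candidate explanation is that 1 read is worth a large FPKM value in a short gene, and differences of an estimated 0.49 to 4.91 reads can then pass as large and even ones. A rise of snoRNA transcripts as a class stays open. The 65 tested snoRNA genes had a median log2 difference of 0.86, and 19 lay above Col-0 without overlap against 8 below (two-sided exact binomial p = 0.0522). The 5.8S rRNA of AT3G41979, also not an mRNA, was at 23211 and 20656 FPKM in Col-0 and at 73081 and 76744 FPKM in mos2-2. For MAPR2, reads assigned to one or the other of 2 neighbouring genes may account for the call, since the summed FPKM with AT2G24945 had a mos2-2 over Col-0 ratio of 1.03.

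Clock genes differed strongly between libraries of one genotype. CCA1 was at 0.485 and 4.41 FPKM in Col-0 replicates 1 and 2 and at 0.76 and 24.2 FPKM in mos2-2 replicates 1 and 2, and the photosynthesis gene LHCB2.2 at 55.4, 2834, 852 and 4858 FPKM. The lower depth of Col-0 replicate 1 is argued against, because the median absolute replicate difference of the clock genes was 1.99 in mos2-2, whose libraries had similar depth, and 2.14 in Col-0. A sampling difference shared by libraries of one replicate number, such as the hour of harvest, may contribute but stays open. Across 20 clock genes, which are not independent, replicate differences in the genotypes had Pearson r = 0.44 (permutation p = 0.051, adjusted 0.076 over 3 lists) and Spearman rho = 0.49 (permutation p = 0.031, adjusted 0.093), so it missed the threshold after adjustment. The 11 reference genes gave r = 0.60 (permutation p = 0.044, adjusted 0.076) and rho = 0.45 (permutation p = 0.16, adjusted 0.24), no lower an r than the clock, and 13 phosphate starvation genes gave r = 0.38 (permutation p = 0.2, adjusted 0.2) and rho = 0.35 (permutation p = 0.25, adjusted 0.25). No biological explanation was tested.

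Other splits of the 4 libraries are too few to give a share under 0.05. The genotypes gave 12 genes past the threshold, and the highest other split, by replicate number, gave 29.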
